A study of Ovis aries with 13 samples.

How the data were processed

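The series holds left ventricle samples of sheep, 6 labelled fetal (gestational day 142) and 7 labelled newborn (postnatal day 1). The design text speaks of 7 fetuses and of further heart regions, and those samples were not analysed here. Per the labels' protocols, frozen tissue was extracted with Trizol, treated with DNase and labelled with Cy3, while the label field names Cy5. The deposited scanner files hold a single green channel, so they were read as 1-colour arrays. The labels give each animal a number, and 9 animals share 4 numbers with another of their group under different letters. What a shared number means is not given in the sources used here.

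The deposited scanner files hold spot intensity values made with Agilent Feature Extraction, per the file headers. The processed signal is an intensity from which background was subtracted and which was detrended within the array, per the file headers, with no normalization between arrays. The mean signal and the local background are raw intensity values. The authors' deposited series matrix holds, judged from the values, log2 signals of 7041 probes, 7016 of them well above background on all 13 arrays. Its scale and normalization are not stated in the sources used here. Each of its columns has a median between 8.69 and 8.70 and correlates best with the log2 signal of its own array (r 0.986 to 0.992), so it was read as not centred by gene, and used only as an alternative.

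The log2 of the processed signal minus the 75th percentile of each array over non-control spots was the value used. Control spots and spots with an outlier mark were left out, and the spots of a probe were averaged. A probe was tested if well above background on at least 6 arrays, the size of the smaller group, which kept 10257 of 15008 probes. Of the 15008 probes, 1738 (11.6%) carried a single gene name after the names and accessions in the files were updated through the RefSeq gene table. Of those 64 had only a LOC number, and 14 probes with several genes, 5 with conflicting names and 13251 with none were left unnamed. A gene was represented by its brightest probe. Of 297 genes with more than 1 tested probe, 81 had a probe that passed, 45 had all their probes pass in the same direction, and 1, IL18, had probes that passed in both directions (-0.55 against 1.71 and 1.67).

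Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Age was the only term of the first comparison, sex was added for the second, and the product of age and sex for the third. The SE is that of the moderated fit. A gene not well above background on any array of a group has a bound there. Its fold is the mean of the bright group over the mean of the dim group, in which each array takes the higher of the probe's own value and the lowest value well above background. Gene lists were written for pathways of the heart at birth and for other cell types a piece of ventricle can hold. Of 44 lists, 42 had a tested member and 18 had at least 5, and these 18 were tested with camera over the 694 named genes at a preset inter-gene correlation of 0.01. Version 1.17.8 of data.table read the files, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

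The design, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule takes 26 fixed genes where they have a tested probe (11 did), the 8 largest rises and the 8 largest falls among named genes that passed, and the members with the smallest p of each list, 2 for a list not called. It gives 84 genes, of which 55 passed, and those described are a part of them. Other genes are named as chosen after their values were seen. The steps were tested on simulated data with the spread of these arrays and 10257 probes. For age, changes of 1.5-fold were recovered for 42% of 50 probes, 2-fold for 90% and 4-fold for 100%, with 4 false calls. For sex they were recovered for 34%, 96% and 96%, with 12 false calls. Only 50 probes at each fold were changed, while 2366 passed for age in the data. The adjustment depends on the share of changed probes, so the rates for age need not hold there. A shift of -0.5 in the 10 glycolysis members was called, with 0 false calls among the lists. The simulated genes varied independently, while the correlation estimated from the arrays reached 0.739 in the interferon list. The simulation thus does not show how often correlated lists are called falsely.

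The slides hold both groups, so slide was tested as a block and within each slide. The effect of slide itself passed for 0 probes in limma, with 533 at an unadjusted p under 0.05. The alternatives were normexp background correction with an offset of 50, quantile normalization, the series matrix, other filters on dim probes, slide, sex, replicate number or animal number in the model, a trended and robust eBayes, each array left out in turn, a fold threshold of 1.5, the mean of a gene's probes and an estimated inter-gene correlation. Normexp fitted by maximum likelihood, normexp with the median background of each array, and newborn 3 and newborn 6 left out together were added later, after the data were seen.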

Results

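Transcript levels were measured in pieces of the left ventricle of sheep hearts, with 1 Agilent 1-colour array for each animal. The labels place 6 arrays in a fetal group at gestational day 142 and 7 in a newborn group at postnatal day 1. The fetal group held 2 females and 4 males, and the newborn group held 4 females and 3 males. The arrays lay on 2 slides, with 4 fetal and 3 newborn arrays on slide 1 and 2 fetal and 4 newborn arrays on slide 2. The 75th percentile of the processed signal lay between 219 and 367 on the 13 arrays, which was 8.77 to 13.6 times the median background. Between 9411 and 10720 of the 15008 probes, or 62.7% to 71.4%, were well above background on each array. The number of arrays limits the precision of every value given.

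The first principal component of the 10139 tested probes with a value on every array held 36.8% of the variance and the second 11.9%. The 6 fetal arrays lay between -29.1 and -20.4 on the first component, and 6 of the 7 newborn arrays between 10.1 and 35.1. Newborn 6 lay between the groups at -8.997. The correlation of any 2 arrays of a group was between 0.960 and 0.991, and 0 pairs of arrays held identical values.

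**Figure D1:**
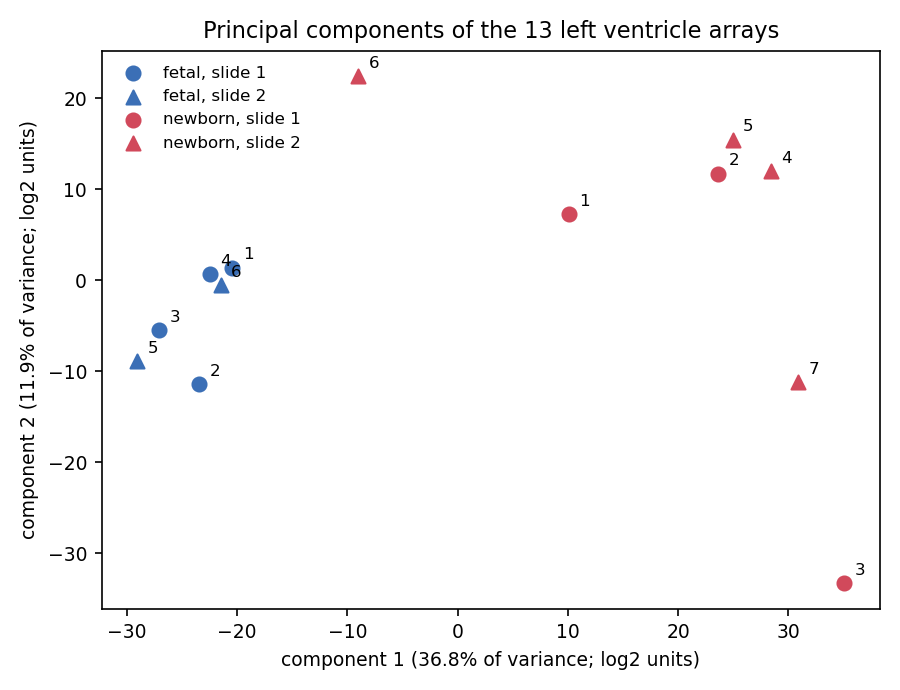
First and second principal component of the log2 values (log2 units) of the 10139 tested probes with a value on every array. Each of the 13 arrays is 1 point, coloured by group, shaped by slide and numbered by replicate. The fetal arrays lie to the left, 6 of the 7 newborn arrays to the right, and newborn 6 lies at -8.997 on the first component.

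The first comparison asked how left ventricle transcripts of newborn lambs differed from those of fetuses close to term, in a series whose title is about metabolic change in the heart at birth. Among the named genes that were higher in newborn ventricles were CPT1A and SLC25A20 of fatty acid entry into mitochondria, the interferon-induced ISG15 and MX1, and PCNA and TYMS of DNA synthesis. Among those that were lower were the glucose transporters SLC2A1 and SLC2A4, insulin-like growth factor 2 (IGF2), the VEGF receptor FLT1, the T-cell gene CD3E and the globin HBB. No list of genes passed as a whole. Among all 694 named genes 162 passed, 95 up and 67 down, so a few passing members do not set a list apart. The largest rise of a named gene was in FBP2, the muscle form of the gluconeogenic enzyme fructose-1,6-bisphosphatase. FBP2 was not well above background on any fetal array and was on 7 of 7 newborn arrays, at least 7.38-fold higher (limma adjusted p = 2.7e-05). The largest fall was in a fetal beta-globin, which fell by 3.12 on the log2 scale (SE 0.641, adjusted p = 0.00435), and was lower on 4 of 7 newborn arrays than on every fetal array.

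Of 3 genes of the carnitine route, by which long-chain fatty acids enter mitochondria, CPT1A and SLC25A20 rose, and CPT1B passed with 1 of its 2 probes, not the brighter one. CPT1A, the carnitine palmitoyltransferase of the outer membrane in liver and fetal heart, rose 3.54-fold (log2 change 1.83, SE 0.345, adjusted p = 0.00291), with a log2 change of 2.38 within slide 1 and 1.69 within slide 2. SLC25A20, the carnitine-acylcarnitine carrier of the inner membrane, rose 2.25-fold (log2 change 1.17, SE 0.103, adjusted p = 2.7e-05), and was higher on 7 of 7 newborn arrays than on every fetal array. CPT1B, the form of adult heart muscle, differed by 0.33 (SE 0.138, adjusted p = 0.0933), and by 0.35 on its other probe (adjusted p = 0.0439). LPL, which releases fatty acids from circulating triglyceride, fell by 0.62 (SE 0.141, adjusted p = 0.00737). Of 4 tested members of the list for fatty acid uptake and beta-oxidation, 2 rose, 1 fell and 1 did not pass, and adjusted over the list alone 3 rose and 1 fell. These 4 genes are also members of the list of PPAR-responsive genes, of whose 7 tested members 3 rose and 1 fell, or 4 and 1 adjusted over the list alone. By their brightest probes the regulators did not pass, with -0.23 for PPARA (SE 0.104, adjusted p = 0.119) and -0.41 for PPARGC1A (SE 0.169, adjusted p = 0.0943), of whose other 2 probes 1 passed (-0.40, adjusted p = 0.0378). In the list for cholesterol and fatty acid synthesis, 2 of 4 tested members rose and 0 fell, and the same numbers passed adjusted over the list alone. The risers were SCD, which desaturates fatty acids (log2 change 1.00, adjusted p = 0.0034), and SQLE of cholesterol synthesis (log2 change 1.20, adjusted p = 0.0133).

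The glucose transporters SLC2A1 and SLC2A4 fell. SLC2A1, the glucose transporter that is abundant in fetal heart, fell by 1.28 on the log2 scale, or 2.42-fold (SE 0.178, adjusted p = 5.5e-04), and was lower on 7 of 7 newborn arrays than on every fetal array, and 4 of the newborn arrays measured it well above background. SLC2A4, the insulin-regulated transporter of muscle, fell by 0.68 (SE 0.13, adjusted p = 0.00303), again on 7 of 7 arrays. HK1, the hexokinase that starts glycolysis in fetal heart, fell by 0.45 (SE 0.105, adjusted p = 0.00815). These were the 3 falls among 10 tested members of the glycolysis list, in which 0 members rose, and the counts were the same adjusted over the list alone. LDHA, the muscle form of lactate dehydrogenase, differed by 0.49 (SE 0.186, adjusted p = 0.0722), and by 0.51 on its other probe (adjusted p = 0.0488). Its brighter probe passed without newborn 1 (adjusted p = 0.0339) or without newborn 6 (adjusted p = 0.0154). In the list for respiratory complexes III to V, 1 of 7 tested members rose, or 2 adjusted over the list alone. That member was ATP5MC1, a subunit of the ATP synthase ring, with a log2 change of 0.68 (adjusted p = 0.0101), measured on 5 of the 7 newborn arrays, since newborn 1 and newborn 2 had no value. Within slide 1 it changed by 0.26, with 1 newborn array. Its 2 bright probes gave 0.68 and 0.60 and its 2 dim ones -0.88 each. The mean of its probes, which lacks the brightest probe on newborn 1 and newborn 2, had the opposite sign (-0.74, adjusted p = 0.244). BCKDHA, which degrades branched-chain amino acids, fell by 0.78 (adjusted p = 0.00275), the 1 fall among 4 tested members of that list, in which 0 rose.

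Some genes for making nucleotides and copying DNA rose. PSPH of serine synthesis, well above background on 4 fetal arrays, rose 2.66-fold (log2 change 1.41, SE 0.166, adjusted p = 1.9e-04) and MTHFD2, a mitochondrial folate enzyme, rose 2.02-fold (log2 change 1.01, SE 0.187, adjusted p = 0.00257), each on 7 of 7 newborn arrays above every fetal array. TYMS, which makes thymidylate, rose 2.54-fold (log2 change 1.34, SE 0.349, adjusted p = 0.0143), although on newborn 6 it lay below every fetal array (-4.24). PCNA, the sliding clamp of DNA replication, rose 2.25-fold (log2 change 1.17, SE 0.221, adjusted p = 0.00295). In the list for one-carbon, creatine and nucleotide metabolism, 4 of 7 tested members rose and 0 fell, and 5 rose adjusted over the list alone. In the cell cycle list 4 of 10 rose and 0 fell, and again 5 rose adjusted over the list alone. CCNB1, the mitotic cyclin, differed by 0.27 (SE 0.272, adjusted p = 0.488), and by 0.50 without newborn 6 (adjusted p = 0.0466). CDKN1C, an inhibitor of the cell cycle, fell by 1.15 (SE 0.292, adjusted p = 0.0125), the 1 fall among 3 tested inhibitors. None of the 22 tested genes for cytosolic ribosomal proteins passed.

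More genes of growth factor signalling, vessels and matrix fell than rose. IGF2, the main insulin-like growth factor of the fetus, fell by 0.98, or 1.97-fold (SE 0.122, adjusted p = 2.4e-04), and IGFBP5, which binds it, fell by 1.57, or 2.97-fold (SE 0.196, adjusted p = 2.4e-04). Both were lower on 7 of 7 newborn arrays than on every fetal array. IGF2R, the receptor that clears IGF2, fell by 0.82 (adjusted p = 0.00142), and IGFBP4, another binding protein, rose by 0.41 (adjusted p = 0.0157), genes chosen after their values were seen. Among 13 tested members of the insulin and IGF list, 2 rose and 4 fell, or 3 and 5 adjusted over the list alone. FLT1, a VEGF receptor of endothelial cells, fell by 0.82 (SE 0.126, adjusted p = 0.001), and PECAM1, a junction protein of endothelium, fell by 0.51 (SE 0.12, adjusted p = 0.00869). They belong to an endothelial list in which 3 of 6 tested members fell and 0 rose. VEGFA, the growth factor induced by low oxygen, fell by 0.67 (SE 0.166, adjusted p = 0.011). In the hypoxia-inducible list 3 of 5 tested members fell and 0 rose, namely SLC2A1, VEGFA and the glucose transporter SLC2A3 (-0.48, adjusted p = 0.0117, chosen after its values were seen). Counts for the endothelial and hypoxia lists were the same adjusted over the list alone. LTBP4, which tethers latent TGF-beta in the matrix, fell by 1.28 (SE 0.201, adjusted p = 0.00122), and MMP2, a gelatinase, fell by 0.75 (SE 0.15, adjusted p = 0.00392). TIMP1, an inhibitor of such proteases, rose by 0.82 (SE 0.21, adjusted p = 0.0136). Of 14 tested genes for matrix and collagens, 1 rose and 4 fell, as did adjusted over the list alone, among them COL4A1 of the basement membrane (-0.78, adjusted p = 0.0152, chosen after its values were seen). CNN1, calponin of smooth muscle and immature heart muscle, rose 3.56-fold (log2 change 1.83, SE 0.415, adjusted p = 0.00729). INHA, the alpha subunit of inhibin, rose 7.85-fold (log2 change 2.97, SE 0.278, adjusted p = 3.4e-05).

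All 5 tested members of the interferon list rose, also adjusted over the list alone. ISG15, MX1 and MX2 were highest on newborn 2 and newborn 5, and next highest on newborn 4 (2.64, 1.74 and 0.24), and these 3 animals share a number. ISG15 was at 5.17 and 4.21 there and at 0.84 to 2.64 on the other newborn arrays, MX1 at 3.74 and 3.02 against 0.03 to 1.74, and MX2 at 3.001 and 2.53 against -2.26 to 0.24. ISG15, a ubiquitin-like protein of the antiviral response, rose 7.11-fold (log2 change 2.83, SE 0.617, adjusted p = 0.00586), and MX1, an antiviral GTPase, rose 3.86-fold (log2 change 1.95, SE 0.564, adjusted p = 0.0234). MX2, its relative, differed by 2.09 (SE 0.693, adjusted p = 0.042), a call lost with slide as a block (adjusted p = 0.0651). It was also lost without any 1 of the 6 fetal arrays or of newborn 2, 4, 5 and 7 (adjusted p = 0.0522 to 0.0767). IRF1, a transcription factor induced by interferon, rose by 0.94 (adjusted p = 0.00675). CXCL10, a chemokine induced by interferon, rose by 2.14 (SE 0.609, adjusted p = 0.0219), was also highest on newborn 2 and newborn 5 and not on newborn 4 (-3.55), and did not pass with animal number as a random block (2.02, adjusted p = 0.0515). FCGR1A, an Fc receptor of monocytes, rose 4.21-fold (log2 change 2.07, SE 0.304, adjusted p = 7.7e-04), although only 2 fetal arrays measured it well above background, so the size of its rise is uncertain. PSMB8 of the immunoproteasome rose by 1.37 (SE 0.22, adjusted p = 0.00134). Of 4 tested members of the list for antigen presentation and complement, 2 rose and 1 fell, as did adjusted over the list alone.

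SAA3, an acute-phase protein, rose by 1.73 (SE 0.327, adjusted p = 0.00295), and NFKBIA, an inhibitor of NF-kappa-B, fell by 1.08 (SE 0.197, adjusted p = 0.00246). Of 10 tested inflammatory mediators 4 rose and 2 fell, or 5 and 2 adjusted over the list alone. The other fall, IL18 (-0.55, adjusted p = 0.0419, chosen after its values were seen), was lost without fetal 1, 2, 3 or 4 or newborn 3, 4, 5 or 7 (adjusted p = 0.064 to 0.0858), and its other 2 probes rose. Among macrophage and monocyte markers 2 of 5 tested members rose and 0 fell, or 3 and 0 adjusted over the list alone. They were FCER1G, an adaptor of Fc receptors (0.76, adjusted p = 0.00921), and CD14, the endotoxin co-receptor (0.66, adjusted p = 0.0164). The T-cell receptor chains CD3E and CD3D fell by 2.07 (SE 0.373, adjusted p = 0.00228) and by 1.63 (SE 0.281, adjusted p = 0.00184), each on 7 of 7 newborn arrays below every fetal array. Only 5 newborn arrays measured CD3E well above background and only 2 measured CD3D, so the sizes of these falls are uncertain. With the median background of each array in normexp CD3D changed by -0.30 and did not pass, though the offset of 50 in that setting makes changes of dim probes smaller. They were the only 2 tested members of the list for neutrophils and lymphocytes. All 3 tested erythroid markers fell. HBB fell by 1.53 (SE 0.335, adjusted p = 0.00616), and the fetal beta-globin fell more. The call of AHSP, which stabilises alpha-globin and was well above background on 2 newborn arrays (-1.73, SE 0.583, adjusted p = 0.0447), was lost without fetal 2, 3, 4 or 5 or newborn 1, 2, 3, 6 or 7 (adjusted p = 0.0583 to 0.103). Binding of one globin's transcripts by another's probe was not excluded, so the values of single globins are uncertain.

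**Figure D2:**
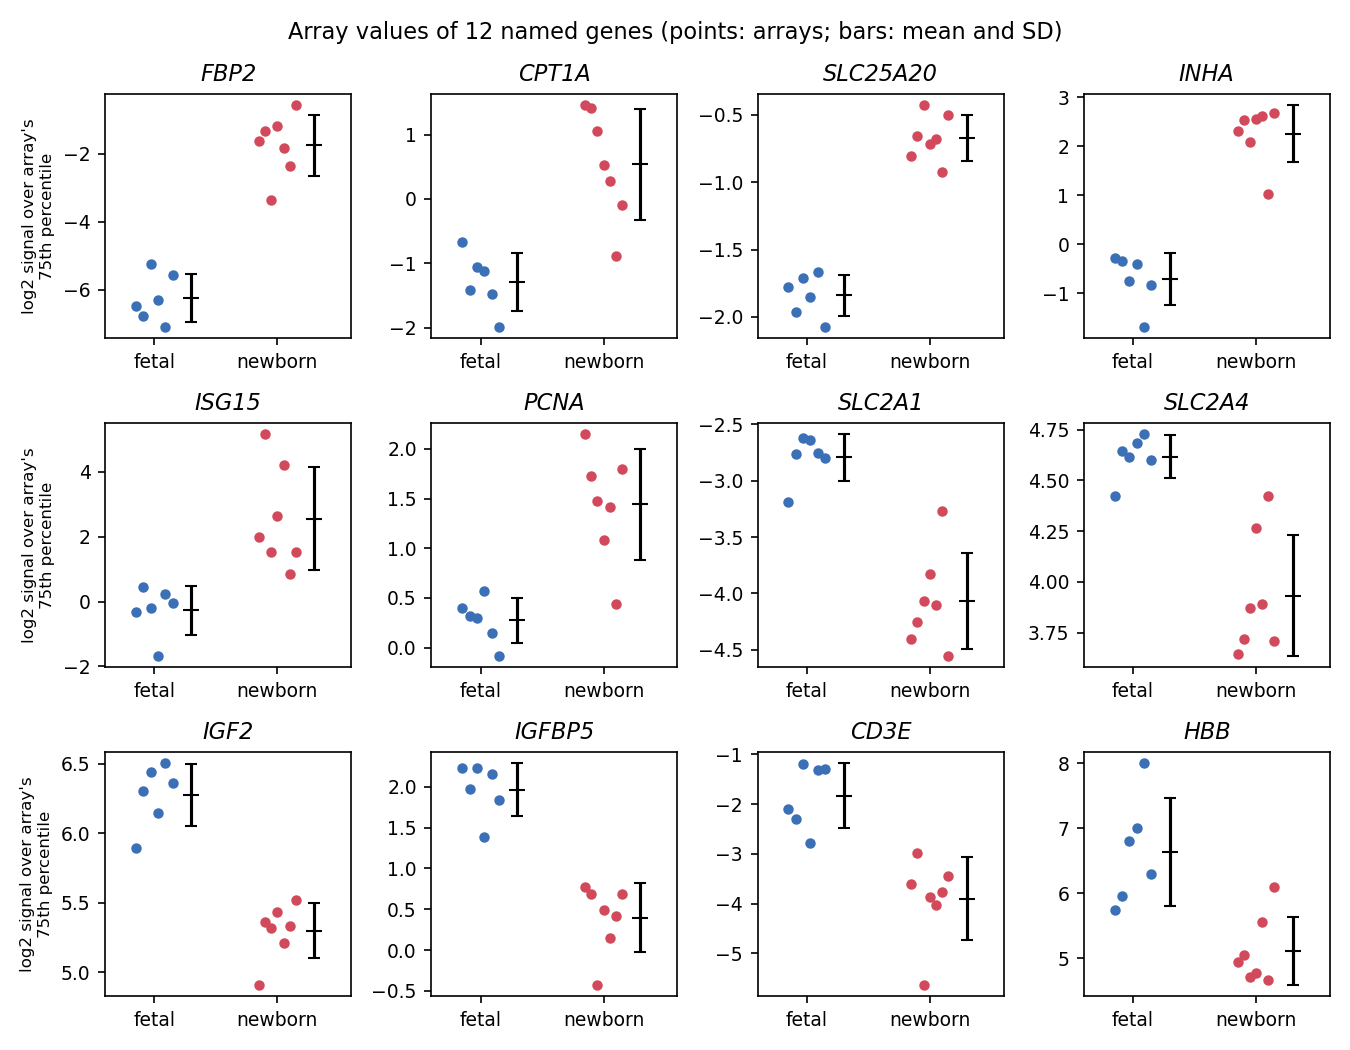
Log2 signal of 12 named genes over the 75th percentile of each array, with 1 point for each of the 6 fetal and 7 newborn arrays and bars for the mean and SD of each group. FBP2, SLC25A20, INHA and ISG15 lie higher on every newborn array than on every fetal array, and SLC2A1, SLC2A4, IGF2, IGFBP5 and CD3E lie lower on every newborn array.

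Across all probes, 2366 of 10257 passed an adjusted p of 0.05 in limma, of which 1227 rose and 1139 fell. At least a 2-fold change was seen in 307 of them, and at least 4-fold in 37. Among 694 named genes 162 passed, with 95 rises and 67 falls, while 2128 of the passing probes had no gene name. With slide as a block 2120 probes passed, and 356 passed within slide 1 and 23 within slide 2. With animal number as a random block 1717 passed. Across all tested probes, which are not independent replicates, the changes in slide 1 correlated with those in slide 2 at r = 0.73. Normexp background correction with the background of each spot left 48 probes, or 43 when fitted by maximum likelihood, and 2011 with the median background of each array. For named genes near background in a group the changes were smaller with the background of each spot, and did not pass, at 1.03 for FBP2, 0.31 for PSPH, 0.39 for TYMS, 0.40 for FCGR1A, 0.67 for CXCL10, -0.41 for SLC2A1 and -0.66 for CD3E. With the median background of each array these 7 passed, again with smaller changes (FBP2 1.36, PSPH 0.50, TYMS 0.64, FCGR1A 0.61, CXCL10 0.96, SLC2A1 -0.33 and CD3E -0.76). Bright genes could lose the call with the background of each spot as well. IGF2, at a fetal mean of 6.27, did not pass in either fit of that kind. Its change lay between -1.13 and -0.91 in every alternative. Every normexp setting added an offset of 50 to each signal. The median processed signal of an array was between 41.7 (newborn 4) and 69.7 (fetal 2). An offset of that size makes changes of dim probes smaller by construction, so the smaller sizes cannot be laid to background alone.

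As whole groups, 0 of the 18 lists with at least 5 tested members passed in limma's camera test, 8 at an unadjusted p under 0.05. With an inter-gene correlation estimated from the data in place of the preset one, 0 passed and 1 had an unadjusted p under 0.05, so there was no call to hold. The smallest adjusted p was 0.0551, for the interferon list (mean log2 change 1.71) and the one-carbon list (0.68), and with an estimated correlation these had adjusted p = 0.398 and 0.318. With slide as a block both passed at adjusted p = 0.0373, as did the cell cycle list (0.0635 without the block, 0.423 with an estimated correlation, mean 0.58). Within slide 1 and slide 2 the mean changes were 1.97 and 1.36 for interferon, 0.75 and 0.65 for one-carbon, and 0.89 and 0.41 for the cell cycle. The insulin and IGF list (mean -0.27, within slides -0.22 and -0.36), the hypoxia list (-0.43, -0.44 and -0.44) and the endothelial list (-0.27, -0.21 and -0.27) each had adjusted p = 0.0635. With slide as a block these had 0.0786, 0.0632 and 0.0786. The PPAR list (mean 0.55, within slides 0.62 and 0.53) and the matrix list (-0.16, -0.17 and -0.09) had adjusted p = 0.0925. The glycolysis list (-0.19, -0.29 and -0.13) and the macrophage list (0.50, 0.45 and 0.52) had 0.0977.

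**Figure D3:**
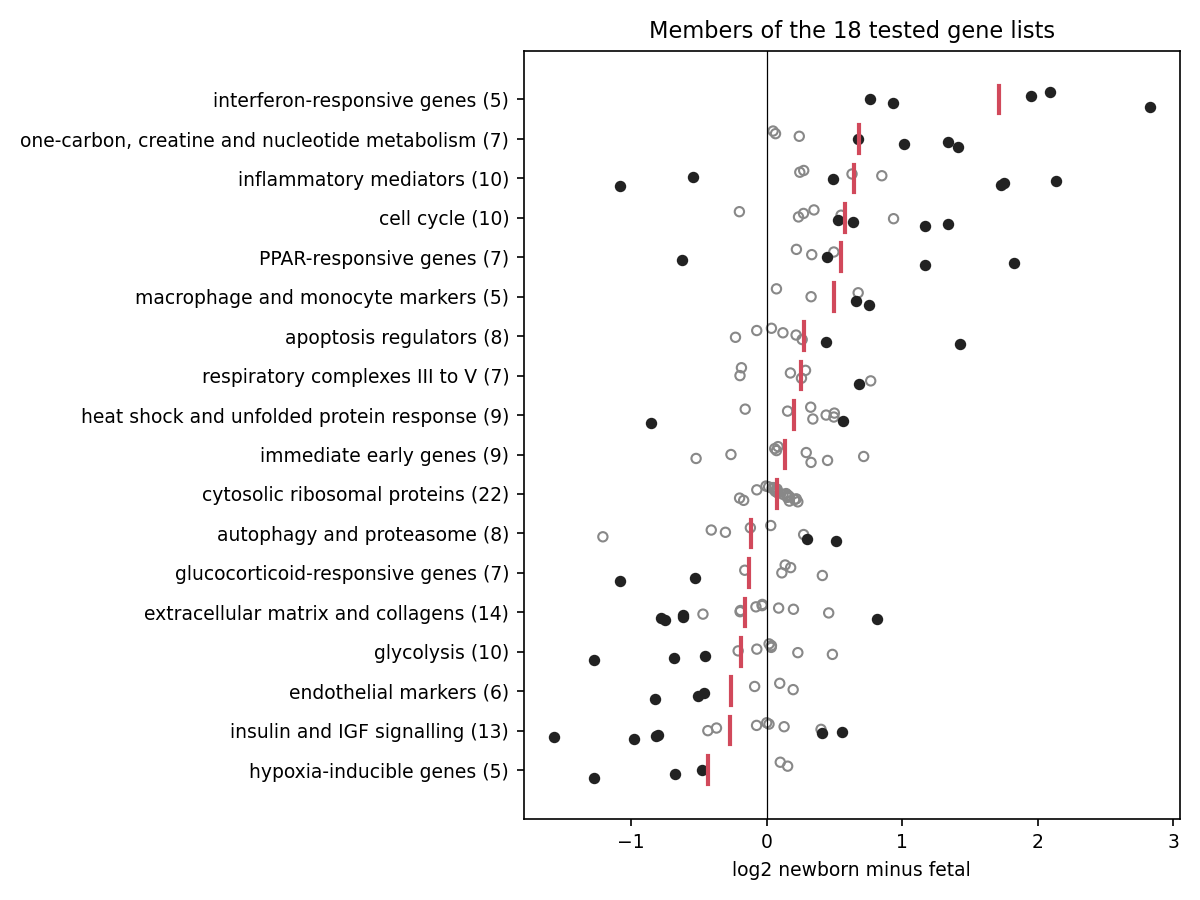
Log2 change, newborn minus fetal, of the tested members of the 18 lists with at least 5 of them (number of members in brackets). Filled points are genes that passed an adjusted p of 0.05, open points are genes that did not, and vertical bars are list means, which run from -0.43 for hypoxia-inducible genes to 1.71 for interferon-responsive genes.

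The second comparison asked whether transcripts differed between females and males with age in the model. A single probe, A_70_P066011, which has no gene name, differed, and was chosen after its values were seen. It was well above background on 7 of 7 male arrays, with signals of 191 to 336, and on 0 of 6 female arrays, with signals of 2.22 to 3.47. It was at least 21.3-fold higher in males (adjusted p = 5.6e-12), and it divided the 13 arrays as the sex labels do. No named gene passed (smallest adjusted p = 0.999), and 331 probes, or 3.23%, had an unadjusted p under 0.05 in limma.

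The third comparison asked whether the change from fetal to newborn differed between females and males. In limma 0 probes passed, 507 (4.94%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.430. The fetal females numbered 2, and simulated interactions of 2-fold were recovered for only 16% of changed probes and those of 4-fold for 84%. A count of 2 probes passed without fetal 2, which leaves 1 fetal female assumed to vary like the other groups, and 1 probe without newborn 3 or newborn 4.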

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

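The 3 tests of newborn 6 were chosen after its position had been seen. A single array lay far from the rest of its group, by Dixon's criterion, in 15 of 195 groups of values examined, where chance gives about 1 in 20, or 9.75.

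Newborn 6 lay between the groups, at a position of 0.355 where 0 is the fetal mean and 1 the newborn mean, and its median correlation was 0.977 with fetal arrays and 0.973 with newborn arrays. An exchange with a fetal array was argued against, since the highest position of a fetal array was 0.154. A fetal heart under a wrong label was argued against as well, since newborn 6 lay 3.48 SD above the mean position of the fetal arrays. A weak hybridisation was argued against by its 75th percentile of signal over background of 10.3, within the 8.77 to 13.3 of the other newborn arrays. No biological explanation was tested, and without newborn 6 the number of probes that passed was 3116 in place of 2366.

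On newborn 6, CCNB1 was at -2.24 on the log2 scale (other newborn arrays -1.02 to -0.27), INHA at 1.02 (2.08 to 2.69), ME1, which makes NADPH, at -1.08 (-0.05 to 0.57), and SOD2, a mitochondrial antioxidant enzyme, at 1.97 (2.93 to 3.54). CDKN1C was at 3.24 on that array (1.14 to 1.80). Without newborn 6 the change of ME1 was 0.68 and passed (adjusted p = 0.00248).

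On newborn 3, CD3E was at -5.63 (other newborn arrays -4.02 to -2.98) and CNN1 at 6.39 (3.29 to 4.17). On newborn 1 the mitochondrial ribosomal gene MRPL32 was at -2.15 (-1.05 to -0.35). Among fetal arrays, CDKN1B, a cell cycle inhibitor, was at -4.16 on fetal 3 (others -3.38 to -3.00), and passed as a fall of -0.68 without that array (adjusted p = 0.0182), while its other probe passed with it (-0.56, adjusted p = 0.043). COL3A1 was at 1.12 (1.67 to 1.99) and MMP2 at -1.48 (-1.22 to -1.07) on fetal 5. ISG15 was at -1.69 on fetal 4 (-0.33 to 0.44) and SLC2A1 at -3.19 on fetal 1 (-2.79 to -2.62). The ribosomal genes RPS20 and RPS6 were at 7.88 (8.36 to 8.55) and 7.24 (7.57 to 7.76) on fetal 2. The calls of CD3E, CNN1, MMP2, ISG15, SLC2A1, INHA and CDKN1C were the same without the array named.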

How the results depend on the processing

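Of the settings named, normexp by maximum likelihood, normexp with the median background of each array, and newborn 3 and newborn 6 left out together were chosen after the data were seen. The number of probes that differed between newborn and fetal arrays was 1717 to 2458 (main 2366) under the other normalizations, filters and models, 2970 without newborn 3 and newborn 6, and 1726 to 3116 with each array left out, with 1699 to 2301 probes shared. The count of 1717 came with animal number as a random block (estimated correlation within a number 0.178). The exceptions follow. Normexp with the background of each spot left 48 probes, 6 named genes, 1 list and 0 probes for sex. By maximum likelihood it left 43 probes, 6 named genes, 1 list and 0 for sex, and ADRB1 turned to -0.018 and -0.012. On fetal 6 and newborn 1 the lowest spots lay at -24434 and -15197 after subtraction of their background. With the median background of each array 2011 probes and 5 lists passed, so the loss goes with the background of single spots. Slide 1 alone, with 7 arrays, gave 356 probes, 41 named genes and 3 lists, and slide 2 alone, with 6 arrays, gave 23 probes, 4 named genes and 2 lists, fewer samples in each. A change of at least 1.5-fold as well left 1097 probes and 93 named genes, by construction.

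With replicate number as a block (replicate block) 1326 probes and 1 list passed. No sign of a pairing by replicate number was seen, as deviations of same-numbered arrays correlated between -0.071 and 0.054, with 0 of 6 pairs over 0.1. Pairs with one animal number lay on both sides of 0.1 (-0.169 to 0.189), so such low correlations cannot exclude a pairing. For animal numbers, pairs of one group with one number had a median correlation of 0.017, against -0.219 with different numbers. Of 9 animals with a shared number, 6 had an array of that number as the closest of their group. The main comparison treated all animals as independent. Lists that passed numbered 1 with quantile normalization, 8 with no filter on dim probes, 1 with probes well above background on all 13 arrays, 3 with slide as a block, 6 with animal number as a random block, 5 with a trended and robust eBayes, 4 with the mean of a gene's probes, 3 without newborn 3 and newborn 6, and 0 to 7 with each array left out. These were 7 without newborn 2, 4 without fetal 2 or newborn 6, 3 without newborn 4, 2 without fetal 3 or newborn 1, and 1 without fetal 5 or newborn 3 or 7. With animal number as a block and with a trended and robust eBayes, the test was cameraPR on moderated t statistics, not camera. Those counts differ from the main one in test as well as in model. The list results thus depend on the setting, and the cause was not tested. For sex 1 probe passed without any single array, and 0 with probes well above background on all arrays, which leaves that probe out. For the interaction 0 to 2 probes passed with each array left out, 2 without fetal 2 and 1 without newborn 3 or 4, and 1 without newborn 3 and newborn 6.

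The list cytosolic ribosomal proteins turned with quantile normalization (-0.026), the series matrix (-0.038) and slide 1 (-7.0e-04), and by its test without fetal 2 (mean 0.026, range 0.026 to 0.113). RPS6 turned with quantile normalization (-0.019), and TPM1 with the series matrix (-0.046) and slide 1 (-0.012). Slide 1 also turned MRPL32 (-0.033) and the test of the list for respiratory complexes (0.096). Slide 2 turned GLUD1 (0.10) and the tests of the lists for heat shock (0.037) and autophagy (-0.0083). The mean of a gene's probes turned ATP5MC1 (-0.74), IL18 (0.94) and the test of the immediate early list (0.081). The cause of these was not tested, and of them only IL18 passed after turning (adjusted p = 0.00222).

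Of 64 passing genes named by the rule or later, 53 passed with each array left out, and 45 under every alternative but single slides and normexp with the background of each spot. CD3D (-0.30), CEBPB (-0.10) and NR2F2 (-0.19) were lost with the median background of each array, CXCL10 with animal number as a random block, and CD14, MYOG and SQLE with the replicate block. The normexp offset of 50 makes changes of dim probes smaller by construction, those of CD3D, CEBPB and NR2F2 among them. Signals of 8.77 to 13.6 times background at the 75th percentile limit dim probes most.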

Other observations

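The tests of TNNC2 in animals that share a number, and both tests of the T-cell and erythroid markers, were chosen after the result was seen, and so were the gap sizes counted. Protein quality control and stress genes moved in both directions. PSMC4, an ATPase of the proteasome, rose by 0.51 (SE 0.0904, adjusted p = 0.00202), higher on 7 of 7 newborn arrays than on every fetal array. Of 8 tested genes for autophagy and the proteasome 2 rose and 0 fell, or 3 and 3 adjusted over the list alone. The other riser, PSMB7, was lost without fetal 2 or 3 or newborn 2, 4, 5 or 7 (adjusted p = 0.0511 to 0.0689). HSPA1A, the inducible heat shock protein, fell by 0.85 (SE 0.144, adjusted p = 0.0017), the 1 fall beside 1 rise among 9 tested members of its list. The riser, PDIA4, was lost without any 1 array other than fetal 1 and newborn 1 and 6 (adjusted p = 0.0549 to 0.0997). Of 8 tested apoptosis regulators 2 rose and 0 fell. These were BCL2, lost without any 1 array other than newborn 3, 5 and 6 (adjusted p = 0.0507 to 0.0789), and FAS, well above background on 2 fetal arrays and lost without fetal 1, 3, 4 or 5 or newborn 2, 3 or 4 (adjusted p = 0.063 to 0.0742).

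Of 9 tested immediate early genes 0 passed in limma and 4 had an unadjusted p under 0.05. JUNB (0.45, adjusted p = 0.0668) passed without fetal 1 or 4 (adjusted p = 0.0197 and 0.0476), and ZFP36 (0.33, adjusted p = 0.0502) without fetal 4 or newborn 1 or 3 (adjusted p = 0.0209 to 0.0365). Of 7 glucocorticoid-responsive genes 2 fell and 0 rose, and these were NFKBIA and the transcription factor CEBPB (-0.53, adjusted p = 0.0132). In the camera test the adjusted p of the heat shock, immediate early and ribosomal lists was 0.698, of the autophagy list 0.823, of the apoptosis list 0.562, of the glucocorticoid list 0.303, of the respiratory list 0.330 and of the inflammatory list 0.167.

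Of 4 tested adipocyte markers 2 fell and 0 rose, LPL and PPARG, the latter lost without fetal 1, 2, 5 or 6 or newborn 2, 3, 4, 5 or 7 (adjusted p = 0.0664 to 0.0843). Of 3 tested skeletal muscle markers 2 rose and 0 fell, MYOG, a myogenic factor (0.91, adjusted p = 0.0173), and MYOD1, lost without any 1 array other than fetal 1 and 4 and newborn 3 (adjusted p = 0.0555 to 0.101). The 1 tested epicardial marker, WT1, fell by 0.50 (adjusted p = 0.0297), and was lost without fetal 2, 3 or 5 or newborn 3, 4 or 5 (adjusted p = 0.0515 to 0.0628). BCL2, MYOD1, PSMB7 and WT1 each passed with only 1 of 2 probes. NR2F2, an atrial transcription factor, fell by 0.57 (adjusted p = 0.00958), on 7 of 7 newborn arrays below every fetal array. Of 2 tested smooth muscle markers 1 rose, CNN1, and of 4 tested genes of the fetal programme of heart muscle CNN1 rose and IGF2, SLC2A1 and HK1 fell. In limma 0 members passed of the lists for glycogen (3 tested), mitochondrial biogenesis (4), respiratory complex I (1), mitochondrial ribosome (1), ketone bodies (1), phospholipids (2), sarcomere (1), calcium handling (2), thyroid hormone (3), antioxidant enzymes (3) and fibroblasts (4). The lists for the citric acid cycle and for neuronal and Schwann cells had 0 tested members. Chosen after their values were seen, the clock gene BMAL1 fell by 1.25 (SE 0.242, adjusted p = 0.00329), the calcium-binding S100A4 rose by 1.77 (SE 0.262, adjusted p = 7.7e-04), and the cytokine TNF rose by 1.75 (SE 0.364, adjusted p = 0.00459). TNF was well above background on only 2 of 6 fetal arrays, so the size of its rise is uncertain. It changed by 0.36 with normexp and the background of each spot, a setting whose offset makes changes of dim probes smaller.

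TNNC2, troponin C of fast skeletal muscle, was high on 7 arrays of both groups and low on 6, with a gap of 3.79 log2 units, or 13.8-fold, between them. Skeletal muscle RNA in some pieces may be the source, and the test set beforehand, a span of NEB of at least 2 log2 units, was met at 2.59. A MYOG probe well above background on only 1 array spanned 2.39, so a span of that size can arise near background and decides nothing. The NEB probe was itself well above background on only 12 arrays. NEB was also lowest on fetal 4 (-5.22), where TNNC2 was high (3.84). The second probe of TNNC2 divided the arrays in the same way, with a gap of 3.36. Among 10139 tested probes with a value on every array, 0 other than those of TNNC2 did so with a gap over 1. With a gap over 0 there were 17. Skeletal muscle RNA would carry other muscle transcripts, so this argues against it as the source, for the transcripts the array covers. Gaps over 2 with at least 3 arrays on either side were found in 9 probes. Of these 6, those of TNNC2 included, followed neither age nor sex. The widest of the 6 was 4.19, on A_70_P017031, which has no gene name. A difference shared by animals with one number stays open, with a permutation p of 0.0547, and 5 of 6 pairs with one number on the same side of the gap. No biological explanation was tested.

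The falls of T-cell and erythroid markers may come from less blood in the newborn pieces. Over 13 arrays the deviations of CD3E and HBB from their group means correlated at r = 0.311 (95% interval -0.32 to 0.75, permutation p = 0.290) and rho = 0.412 (permutation p = 0.196). Without the 2 arrays farthest from the median r was 0.484, and within the slides it was 0.214 and 0.381, so this stays open. Fewer leukocytes of every kind would lower macrophage and monocyte markers as well, and of the 5 tested 2 rose and 0 fell. Their mean change was 0.50 and that of the CD3 genes -1.85, a difference of 2.35 (SE 0.365, exact p = 5.8e-04 over all splits). That p adds little, since the CD3 genes were taken after they were seen to lie lower on 7 of 7 newborn arrays. Transcript levels do not count cells, so this explanation stays open as well. The age of the animals stays open as an untested explanation.

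Chance can be excluded for the number of probes that differed with age, since 1 of 100 splits of the 13 arrays, the real one, gave as many as 2366, and the highest other gave 816. These splits treated the arrays as independent, although 9 animals share a number with another of their group. The split by slide gave 1 probe. For the lists the smallest unadjusted camera p was compared, since 0 passed. Chance cannot be excluded there, as 59 of 100 splits gave a p as small as the real 0.00307, with 2.0e-08 the smallest, and another split called 5 lists. The split by slide gave 4.8e-04, and with slide as a block 3 lists passed. For sex 4 of 100 splits gave at least the real count of 1, a share under 0.05, and the highest other gave 10. A count of 1 probe that other splits reach or exceed cannot exclude chance. The separation of A_70_P066011 between the sexes did not enter this test.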
